A study of Bos taurus with 12 samples.

How the data were processed

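Liver RNA from 12 Holstein calves, 6 heat-stressed and 6 cooled, was sequenced, and 1 table of read counts per gene was used for each calf. The deposited values are whole-number counts, not normalized. Per the submitters' processing notes, the tools were FastQC 0.11.7, Trim Galore 0.4.4, HISAT2 and HTSeq, with the genome build ARS-UCD1.2. The versions of HISAT2 and HTSeq, the annotation release and the strand setting of the counting are not given in the sources used here. How reads from overlapping or antisense genes and from near-identical gene copies were counted is therefore not known here. RNA was extracted with a column kit and the libraries were made and sequenced by a commercial provider, per the labels' protocols, and no date, lane or batch is given in the labels.

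Each library was assigned to its group from the treatment in the labels. The series description counts 6 calves per group, and each library was taken as 1 calf. The labels give no replicate numbers, so calves were numbered within a group in listing order and not paired. Where libraries come from fewer animals than that, the p-values measure a spread that is partly technical. This bears on cooled calves 2 and 3, described in the results.

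Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr on the group, which left 14924 of 27570 (54.1%). Library sizes were scaled by TMM factors. Dispersions were estimated with estimateDisp, and the groups were compared with glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are heat-stressed over cooled. The SE of a log2 fold change was taken from the fold change and the F statistic, and its 95% interval from the t quantile at the fitted degrees of freedom. Log2 CPM used a prior count of 2. Alternatives used DESeq2 1.42.0, limma 3.58.1 and sva 3.50.0.

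Whole profiles were compared in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. The pseudo-F statistic on Euclidean distances of log2 CPM was tested over all 924 assignments of the labels. For the spread between calves, the distance of each calf to its own group's centroid was computed and the distances were permuted exactly. The smallest p this two-sided test can give is 0.00216. Where a group had 5 libraries, distances were scaled to a group of 6, since a centroid of fewer calves lies closer to each of them. Pairs of libraries were compared by their biological coefficient of variation, and by a chi-square test per gene with at least 50 counts summed over the pair.

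The tests between the groups, most alternatives and the rule for naming genes were set before the data were examined. That rule took genes with a symbol by their p, and 43 lists with 1222 genes were fixed for a camera test. None of the 27570 identifiers matched the gene table used here, so neither the list tests nor the naming by symbol could be run. In their place the 2 identifiers with the smallest p in each direction among the genes kept by the filter are given. Alternatives covered the normalization, the filter, the test, a surrogate variable, the thresholds and leaving out each calf. The planned older form of the edgeR fit (legacy=TRUE) is the default of the installed version and so is the main result, and the newer form was run instead. Chosen after seeing the data were that newer form, the sum of cooled calves 2 and 3, DESeq2 on the genes tested by edgeR, the removal of the 20 most abundant genes without the mitochondrial genes, a second permutation scheme for the spread, the tests on the pair of cooled calves 2 and 3, and the predictions for the counts over other splits of the calves.

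The gene-level tests were tested on simulated counts for 6 against 6 calves with 14764 genes tested and a known set of genes changed. At adjusted p under 0.05, edgeR recovered 10.4% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 90.9% of those changed 4-fold, with 6.36% of its calls false. DESeq2 recovered 16.4%, 76.1% and 93.9%, with 17.9% of its calls false. The profile tests were tested on simulated profiles with a known shift and a known difference in spread.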

Results

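The study asked whether housing Holstein dairy calves under heat stress, rather than with cooling, between birth and weaning changed gene expression in the liver. Liver was sampled by biopsy at 42 days of age from 6 heat-stressed and 6 cooled calves, and total RNA was sequenced, giving 1 table of read counts per calf. Each table listed 27570 genes, of which 21975 had at least 1 count in some calf. Total counts ran from 24791222 to 31074009 in the cooled calves and from 22910846 to 32240168 in the heat-stressed calves. The difference between the groups' mean totals was within the spread between calves (p = 0.379, two-sided exact permutation test). Between 18174 and 18977 genes had a count in a single calf. At these totals a count of 0 allows up to 0.0931 CPM (the count of a gene scaled to a common library total) in the deepest library and up to 0.131 CPM in the shallowest, for counting error only. The calf numbers used here only name the libraries within a group. The tables give genes as Ensembl identifiers and do not pair them with symbols. For the main comparison 2 identifiers are therefore given in each direction, and no gene names.

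The main comparison was heat-stressed against cooled calves for each of 14924 genes with enough counts to test. ENSBTAG00000012604 had the smallest p of these 14924 genes. It stood at 0.496 CPM ± 0.0829 (SD, n = 6) in cooled and 1.79 CPM ± 0.736 (SD, n = 6) in heat-stressed calves, a 3.58-fold higher level (log2 fold change 1.84, SE 0.327). This is a low-abundance gene, with 11 to 69 reads per calf. ENSBTAG00000010206 was measured far more deeply, at 1456 to 4370 reads per calf. Its level was 63.9 CPM ± 5.66 (SD, n = 6) in cooled and 114.7 CPM ± 34.3 (SD, n = 6) in heat-stressed calves, a log2 fold change of 0.84 (SE 0.176). In the other direction, ENSBTAG00000006261 stood at 15.5 CPM ± 1.32 (SD, n = 6) in cooled and 9.45 CPM ± 1.98 (SD, n = 6) in heat-stressed calves, a log2 fold change of -0.72 (SE 0.149). ENSBTAG00000040555 stood at 12.9 CPM ± 1.23 (SD, n = 6) in cooled and 8.55 CPM ± 1.25 (SD, n = 6) in heat-stressed calves, a log2 fold change of -0.59 (SE 0.134). For each of these genes, 6 of 6 heat-stressed calves lay outside the range of the cooled calves. For ENSBTAG00000012604 the margin was within counting error. Heat-stressed calf 3 stood at 0.582 CPM from 14 reads, and the highest cooled calf, calf 4, at 0.578 CPM from 18 reads. The genes were picked for their small p among 14924, so this separation is in part a product of the choice.

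**Figure D1:**
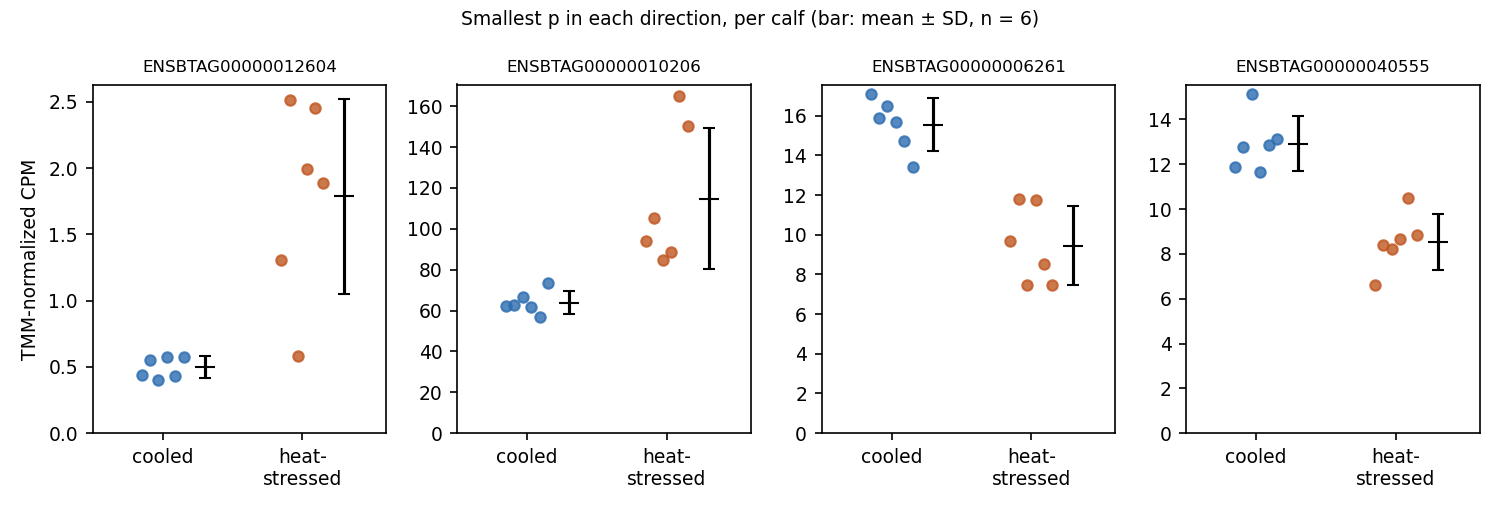
TMM-normalized CPM (vertical axes, each from 0) of the 2 genes with the smallest p in each direction, with 1 point per calf and a bar at the mean ± SD (n = 6 per group). The heat-stressed calves lie above the cooled calves in the left pair of panels and below them in the right pair, with heat-stressed calf 3 at 0.582 CPM in the first panel, next to the highest cooled calf at 0.578 CPM.

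None of these differences passed the correction for the number of genes. With edgeR's quasi-likelihood test, 0 genes were higher and 0 were lower in heat-stressed calves at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p, shared by all 4 named genes, was 0.524. At an unadjusted p under 0.05 there were 1399 genes, 760 higher and 639 lower in heat-stressed calves, where 746.2 would be expected if no gene differed. DESeq2, run on all 21975 genes with a count, called 7 genes higher and 6 lower at adjusted p under 0.05, among them the 4 named genes. A further 3 of its calls were genes that the filter had left out of the main edgeR test. Without that filter, edgeR still called 0 higher and 0 lower. On the 14924 genes tested by edgeR, DESeq2 called 10 higher and 7 lower, and limma-voom called 0 and 0. With cooled calves 2 and 3, whose libraries were unusually alike, summed into 1 library, DESeq2 called 2 higher and 1 lower over all genes with a count. Without heat-stressed calf 3, edgeR called 1 gene, ENSBTAG00000012604, higher in heat-stressed calves (edgeR adjusted p = 0.0224), and the number at unadjusted p under 0.05 was 2578. It was 857 without heat-stressed calf 1 and 841 without heat-stressed calf 6.

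The intervals give the precision of each gene's fold change. Each is a 95% interval for a single gene, not adjusted for the number of genes, so some of them are expected to miss the true value. They also count the unusually alike pair of cooled libraries as separate calves. If that pair shares an animal, the intervals could be too narrow. The 95% interval of the fold change lay within a 2-fold change either way for 12378 genes (82.9%) and within a 1.5-fold change for 5619 genes (37.6%). Precision was lowest for the least abundant genes. The median SE of the log2 fold change was 0.398 over 1407 genes under 1 CPM, 0.238 over 4993 genes from 1 to 10 CPM, 0.171 over 7170 genes between 10 and 100 CPM and 0.191 over 1354 genes at 100 CPM or more. The 2-fold bound held for 29%, 79.2%, 94.6% and 91.3% of them. Between 10 and 100 CPM, 11.3% of genes had an unadjusted p under 0.05, 410 of them higher and 397 lower in heat-stressed calves. Under 1 CPM the share was 5.83%, with 60 higher and 22 lower.

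Whole profiles were compared next. The groups did not separate beyond the spread between calves. Group accounted for 11.7% of the variation in log2 CPM (pseudo-F 1.33, p = 0.169, exact permutation test over 924 assignments of the labels). The first principal component held 31.5% of the variance. On it, heat-stressed calves 1, 2 and 6 scored 52.3, 43.8 and 55.7, cooled calves 1 and 6 scored 13.8 and 10.3, and the other 7 calves scored between -32.8 and -18.1. The group means on this component, 12.4 ± 42.1 (SD, n = 6) in heat-stressed and -12.4 ± 19.8 (SD, n = 6) in cooled calves, did not differ beyond that spread (p = 0.219, two-sided exact permutation test). Of 5 components tested, the fourth had the smallest p (0.0303, exact permutation test, 0.152 after Benjamini-Hochberg adjustment).

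**Figure D2:**
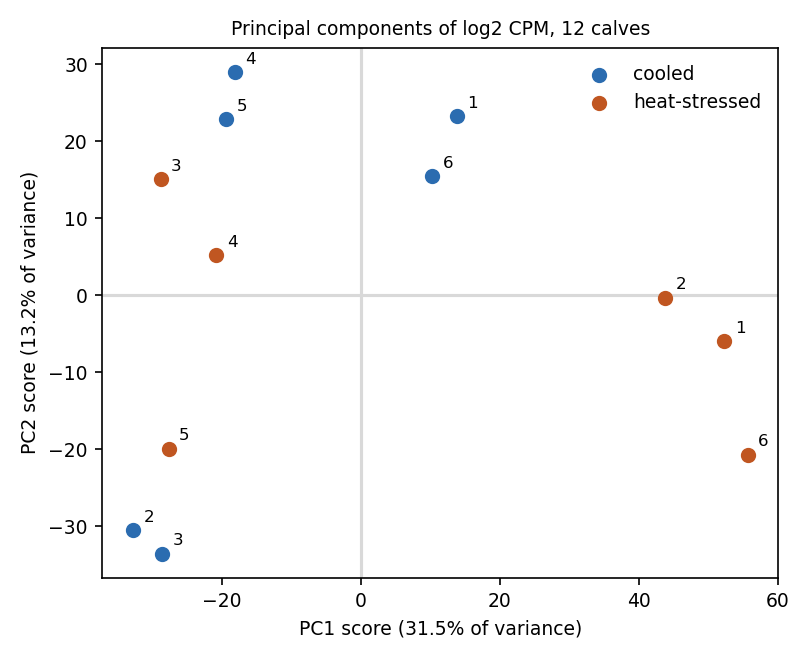
Scores of the 12 calves on the first (horizontal) and second (vertical) principal components of log2 CPM, with 1 point per calf, numbered within its group. Heat-stressed calves 1, 2 and 6 lie at the right, from 43.8 to 55.7 on the first component, and cooled calves 2 and 3 lie together at the lower left.

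The heat-stressed calves lay farther from their own group's centroid than the cooled calves did. The mean Euclidean distance in log2 CPM was 58.5 ± 3.97 (SD, n = 6) in heat-stressed and 49.8 ± 1.93 (SD, n = 6) in cooled calves, a difference of 8.77 (p = 0.00433, two-sided exact permutation test of the distances). Of the heat-stressed calves, 5 of 6 lay farther from their centroid than any cooled calf did, the exception being calf 2 at 51.6. Over the 500 most variable genes alone the difference was -0.341 (p = 0.673, exact permutation test), so the wider spread was not seen in the genes that varied most between calves. The distances in a group share 1 centroid and are not independent. A split of the group along 1 axis moves all of them outward. On the first principal component the SD of the scores was 42.1 in heat-stressed and 19.8 in cooled calves. It was 14.1 and 28.6 on the second and 17.5 and 16.8 on the third. On the fourth it was 18.6 and 9.60, and on the fifth 17.2 and 16.7. In summed squared distance, the heat-stressed calves exceeded the cooled calves by more on the first component than over the whole profile. The other components together were therefore not wider in heat-stressed calves. No permutation test was run without the first component.

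**Figure D3:**
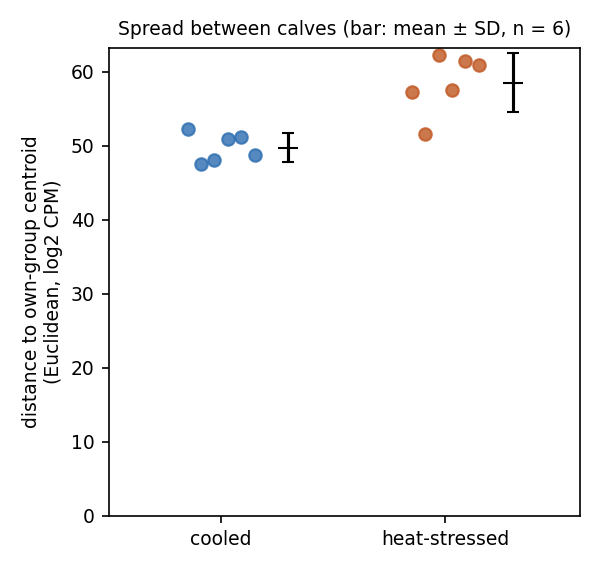
Euclidean distance of each calf's log2 CPM profile to the centroid of its own group (vertical axis, from 0), with 1 point per calf and a bar at the mean ± SD (n = 6 per group). Heat-stressed calves lie from 51.6 to 62.3 and cooled calves from 47.5 to 52.2.

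Cooled calves 2 and 3 were far more alike than any other pair. Their biological coefficient of variation was 0.0571, where the other 65 pairs ran from 0.197 to 0.391, and their log2 CPM correlated across genes at r = 0.990, where the other pairs ran from 0.940 to 0.977. Genes are not independent replicates in such a correlation. Their counts differed by more than counting error, with 26.5% of genes at p under 0.05 in a chi-square test. That test does not show that they came from different animals. They were counted as separate calves because the series description counts 6 per group, and if they share an animal the cooled group holds 5. The tests were therefore repeated with their counts summed. Summed, edgeR again called 0 genes and the difference in spread was 9.07 (p = 0.00866, exact permutation test). The number of genes at unadjusted p under 0.05 fell from 1399 to 991, and the edgeR adjusted p of the 4 named genes was 0.707. Leaving out 1 of the other cooled calves gave from 987 (without calf 4) to 1560 (without calf 1) such genes.

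**Figure D4:**
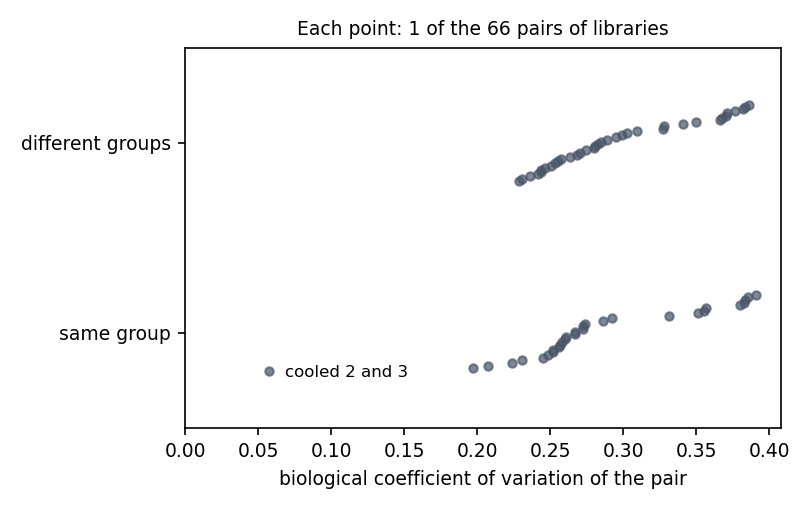
Biological coefficient of variation (horizontal axis, from 0) of each of the 66 pairs of libraries, 1 point per pair, in rows for pairs of the same group and of different groups, with the height within a row only spreading the points. Cooled calves 2 and 3 lie at 0.0571 and the other pairs from 0.197 to 0.391.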

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

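For the 4 named genes, the library measures, the principal component scores and the distances to the group centroid, the calf farthest from the rest of its group was compared with Dixon's critical value of 0.625 for 6 samples. Of 24 sets of 6 calves, 0 exceeded it.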

How the results depend on the processing

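The summing of cooled calves 2 and 3, DESeq2 on the genes tested by edgeR, the newer edgeR fit, the removal of the 20 most abundant genes and the reassignment of whole profiles were chosen after seeing the data. The counts of 0 genes higher and 0 lower held in 23 and 24 of the 26 alternatives that were not stricter than the main test by construction. These included limma-voom, another scaling, no filter, a surrogate variable and an adjusted p under 0.1 in the main edgeR fit. With limma-voom quality weights 0 genes passed 0.05, but the 4 named genes had an adjusted p of 0.0988, which is under 0.1. DESeq2 called 7 higher and 6 lower over all genes with a count, and 10 higher and 7 lower on the genes tested by edgeR, so the difference from edgeR does not come from the filter alone. Of those 17 genes, 10 were also called over all genes. In the simulation DESeq2 also had the larger share of false calls. That simulation used edgeR's own dispersion estimates and held no structure among calves, so it does not decide between the tests here. The cause of the difference was otherwise not tested. Leaving out 1 calf at a time gave 0 to 1 genes higher and 0 genes lower, the 1 being ENSBTAG00000012604 without heat-stressed calf 3. The number of genes at unadjusted p under 0.05 ran from 841 (without heat-stressed calf 6) to 2578 (without heat-stressed calf 3) and was 4126 with limma-voom quality weights. The cause was not tested. The log2 fold changes of the 4 named genes kept their sign under every alternative that gave a value, with ENSBTAG00000012604 between 1.70 and 2.02 and having no value at a minimum of 1 CPM in 6 libraries. Its adjusted p ran from 0.000832 to 0.751. The pseudo-F ran from 1.004 to 1.65 with p from 0.0801 to 0.450 over 21 alternatives. The difference in spread kept its sign and a p under 0.05 in 20 of 21, and was -0.341 over the 500 most variable genes. The cause was not tested. With whole profiles reassigned between the groups, 3 of 462 splits gave a difference as large (p = 0.00649, exact permutation test). Tests of gene lists (camera, fry) and the removal of mitochondrial genes were not run, since identifiers could not be matched to names. No paired analysis was possible because the calf numbers only name the libraries. Depth limits genes under 1 CPM most, where the 2-fold bound held for 29%.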

Other observations

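The tests on cooled calves 2 and 3 and the counts over other splits were chosen after those results were seen. The predictions for the spread and for all DESeq2 calls were written before their results were seen. The summing of cooled calves 2 and 3, which the test on the spread uses, was itself chosen after seeing the data. Cooled calves 2 and 3 had a biological coefficient of variation of 0.0571 against at least 0.197 in other pairs. A single library under both names, differing by counting error alone, is argued against by the 26.5% of genes at p under 0.05 in a chi-square test, where about 5% would be expected. Added variation between runs of a single library was not tested. If a batch does not switch genes on or off, which was not tested, unrelated calves of a shared batch would disagree as other pairs do at genes that were on in some and off in others of the other 10 libraries. The pair disagreed in 4 of 34 such genes (11.8%, exact 95% interval 3.30% to 27.5%), where the other 65 pairs ran from 20.9% to 57.1%. At the rates of those pairs, so few disagreements had a chance of 0.0101, or 0.0122 with genes of the same on/off pattern counted once. The pair had been picked as the most alike of 66, and after multiplying by 66 these are 0.665 and 0.808, so unrelated calves of a shared batch stay open. The libraries may also come from 1 calf or from identical calves, but the 11.8% missed the bound of under 5% written for that, so it stays open too, as does a closer kinship, which was not tested. A second rule, which left out genes with a level in the middle of the gap, was tried only after the first had missed its bound. It gave 1 of 30 genes (3.33%) against at least 21.6% in other pairs, and since it was chosen with the first result in view it decides nothing.

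Chance could not be excluded for the number of genes at unadjusted p under 0.05. Of 100 splits of the 12 calves into 6 and 6, drawn from 462 and with the real split among them, 7 gave at least the 1399 genes of the real split. The highest other split gave 5359, and the median of the others was 404. Of the 54 other splits that kept cooled calves 2 and 3 on the same side, as the real split does, 5 gave as many, with a median of 487. Of the 45 that parted them, 1 did, with a median of 290. At adjusted p under 0.05 the real split gave 0 genes with edgeR, so 100 of 100 splits gave as many by construction, which says nothing about chance. Of the 99 other splits, 14 called at least 1 gene. Of these, 13 called 1 or 2 genes and 1 called 1423, which points to a structure among the calves other than the group. All 14 had cooled calves 2 and 3 on the same side, as the real split does, against 54 of the 99 other splits in all.

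The wider spread of heat-stressed calves, 8.77 in mean distance, could have come from the closeness of cooled calves 2 and 3 drawing in the cooled centroid. With both summed into 1 library the difference was 1.03 times its value, which argues against that explanation. The heat-stressed calves did not lie evenly around their centroid. Calves 1, 2 and 6 scored 52.3, 43.8 and 55.7 on the first principal component, had TMM factors of 1.09, 1.08 and 1.09, and gave 9.82%, 9.58% and 8.49% of their counts to their most abundant gene. Calves 3, 4 and 5 scored -28.8, -20.8 and -27.6, with factors of 0.867, 0.982 and 0.943 and shares of 7.03%, 4.83% and 4.72%. No batch, date or sire is given in the labels, so whether a technical structure of these libraries or heat stress itself gave the wider spread was not tested and stays open.

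Of the 13 genes called by DESeq2 over all genes with a count, 3 were on in some calves and off in others by the same rule applied to all 12 libraries, a share of 0.231, where 0.246% of the 21125 genes with a DESeq2 adjusted p were. That share lies between the bounds set for and against such switching as the source of the calls, at 0.5 and 0.1. The rule takes no account of group, so a large difference between the groups would also meet it. It cannot tell such a difference from switching regardless of group. Genes with large differences also meet it more readily than genes at large, so the 0.246% is not a matched share. The 13 calls are also too few to decide. The 3 are the calls that the filter left out of edgeR's main test, and of the 10 that it did test 0 were such genes. Without the filter edgeR tested the 3 as well, and called 0 genes higher and 0 lower. By DESeq2 log2 fold change, the 3 were ENSBTAG00000039664 (8.39), ENSBTAG00000004272 (-5.03) and ENSBTAG00000043157 (-4.31). Their DESeq2 adjusted p was 3.41e-05, 0.000138 and 0.0322, where ENSBTAG00000012604 had 0.000832. The first had 0 counts in 3 cooled libraries, and the others each in 2 heat-stressed libraries.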
